A study of Homo sapiens with 16 samples.

How the data were processed

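The series deposited 1 table of raw counts per library, with 60448 Ensembl genes. Per the notes of the authors, the counts were made before deposit by aligning reads to GRCh38 with STAR 2.7.1a and counting them per gene with featureCounts. The annotation release, the strand setting and the handling of multiply mapped reads are not given. Symbols, biotypes and coordinates were taken from GENCODE 29, which holds 56868 of the genes (94.1%). The 3580 genes outside it held at most 0.0463% of a library's counts. The deposited values are whole numbers.

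Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Genes were kept by filterByExpr (18285 genes), scaled by TMM and fitted with 1 mean per group over all 16 libraries (8 residual degrees of freedom). Quasi-likelihood tests used robust dispersions, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. In all, 11 pairs of groups and 3 interactions of the epithelial to mesenchymal change were tested. "Rose" and "fell" name the direction of the group written first, also where groups are not stages of 1 process. For a gene at 0 in every library of a group, the fold is a lower bound computed with a floor of 3 counts per library.

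Gene lists were written from textbook knowledge before the data were examined, as were the comparisons, the alternatives and the rule for named genes, apart from those said to be chosen after seeing the data. The 24 lists are epithelial, basal, luminal, mesenchymal, matrix, drivers of the epithelial to mesenchymal transition (EMT), TGF-beta and BMP, Wnt, NF-kB, interferon, antigen presentation, cell cycle, cyclin-dependent kinase inhibitor, cholesterol, hypoxia, developmental transcription factor, HOX, PRC2, COMPASS, sort marker, endothelial, neural, muscle and leukocyte genes. Lists with at least 3 measured genes were tested with camera (preset correlation 0.01, prior count 2), adjusted over 23 lists and 11 comparisons. Of these 253 tests 87 were called, of which 22 held with an estimated correlation. The 69 tests of interactions gave 15 calls, of which 2 held.

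Named genes follow a rule. It takes the 6 highest and 6 lowest log2 changes among called genes with at least 5 CPM in the higher group and a proper symbol, and up to 4 called members of each list with at least 1 CPM. It also takes EED, KMT2D, CDH1, EPCAM, VIM, ZEB1, SNAI2, FN1, CDH2, KRT14, KRT8, CD24, CD44, ITGB4, EZH2, KMT2C, KDM6A and HRAS. Not every gene it takes is printed. Alternatives were RLE scaling, no filter on low counts, a DESeq2 1.42.0 Wald test, fits of only the compared libraries, a replicate block, other controls, and each library left out in turn. A correction of GC content and length (a spline with 4 degrees of freedom per library, over genes with a mean of at least 50 counts), C1 as the only control, and 1 sgControl library for each guide were chosen after seeing the data.

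The pipeline was run on simulated counts with known changes in sgEED libraries. It recovered 5.97% of genes changed 1.5-fold, 52.2% at 2-fold and 87.9% at 4-fold, and called 7 unchanged genes. Simulated counts without changes gave 0 calls. A simulated GC trend gave 6932 calls without the correction and 0 with it. Camera called 10 of 10 shifted lists and 0 of 10 unshifted ones, with no correlation simulated.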

Results

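The series measured RNA in HMLER cells, human mammary epithelial cells immortalized and transformed with introduced genes that include TERT and oncogenic HRAS. It holds 16 libraries in 8 groups of 2. The unedited groups are C1, described as a stable epithelial state, C2-Epi, a plastic epithelial state, and C2-Mes, a mesenchymal state. The edited groups derive from C1 and carry a control guide (sgControl), a guide against EED in epithelial (sgEED-Epi) and mesenchymal (sgEED-Mes) cells, or a guide against KMT2D in the same pair of states (sgKMT2D-Epi, sgKMT2D-Mes). EED is a core subunit of PRC2, the complex that writes repressive methylation on histone H3, and KMT2D is an activating histone H3 methyltransferase of the COMPASS family. Total counts ran from 18872124 (C2-Mes replicate 1) to 31950649 (C2-Mes replicate 2). Levels below are CPM (counts scaled to library totals of 1e6 by TMM), as mean ± SD of the 2 libraries of a group (n = 2). Nothing in the labels says that the 2 libraries of a group are separate cultures, so the p-values measure only the spread between these libraries. Nor do the labels say whether C1 and C2, or the epithelial and mesenchymal cells of 1 guide, come from 1 clone. Differences between them can be clonal as well as of state. The names of the deposited libraries differ between the 2 states of each guide in a part that can mark a clone. The 2 C2-Mes libraries carry names of different kinds, and that of replicate 1 reads as prepared again.

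The libraries separated first by state. The first principal component held 41.6% of the variance. It placed the 6 mesenchymal libraries between 98.3 and 121.3 and the 10 epithelial libraries between -98.7 and -34.6. Replicates correlated across genes with r between 0.988 and 0.994, except in C2-Mes, where r was 0.967 and the log2 differences between replicates had an SD of 0.890 against at most 0.493 in the other groups. Mitochondrial transcripts made up 7.01% to 12.5% of counts, with the highest share in C2-Mes replicate 1. Transcripts of ribosomal proteins made up 6.40% and 7.77% of counts in the sgControl libraries and 3.48% to 5.399% elsewhere. FN1, which encodes the matrix protein fibronectin, took the largest share of any gene, up to 13.2% of all counts in sgKMT2D-Mes. Leukocyte markers, of which only 2 genes were measured and no set test was run, summed to between 0.333 and 1.98 CPM.

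The transcripts of the edited genes are given first. EED (ENSG00000074266, GRCh38 chromosome 11, 86244544 to 86278813) stood at 27.3 ± 1.09 CPM in C1, 24.1 ± 3.52 in sgControl, 28.1 ± 1.99 in sgEED-Epi and 5.36 ± 0.197 in sgEED-Mes. Its level was 18.9 ± 1.18 in C2-Epi, 11.8 ± 0.877 in C2-Mes, 38.2 ± 0.177 in sgKMT2D-Epi and 22.9 ± 1.34 in sgKMT2D-Mes. EED transcripts in sgEED-Epi did not pass the test against sgControl (log2 0.22, adjusted p = 0.22), and turned to log2 -0.59 (adjusted p = 0.074) with a GC and length correction chosen after seeing the data. They fell in sgEED-Mes against sgEED-Epi (log2 -2.39, adjusted p = 3.8e-08). KMT2D (ENSG00000167548, chromosome 12, 49018975 to 49059774) stood at 86.1 ± 8.33 CPM in C1, 80.4 ± 13.4 in sgControl, 115 ± 0.672 in C2-Epi and 104 ± 27.9 in C2-Mes. Under its own guide it stood at 126 ± 1.84 in sgKMT2D-Epi, above sgControl (log2 0.64, adjusted p = 0.0067, and 0.057 without sgControl replicate 2), and at 81.7 ± 6.92 in sgKMT2D-Mes. A guide can inactivate a protein without lowering its transcript, and gene counts hold no sequence, so these values do not show whether either gene was disrupted.

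**Figure D1:**
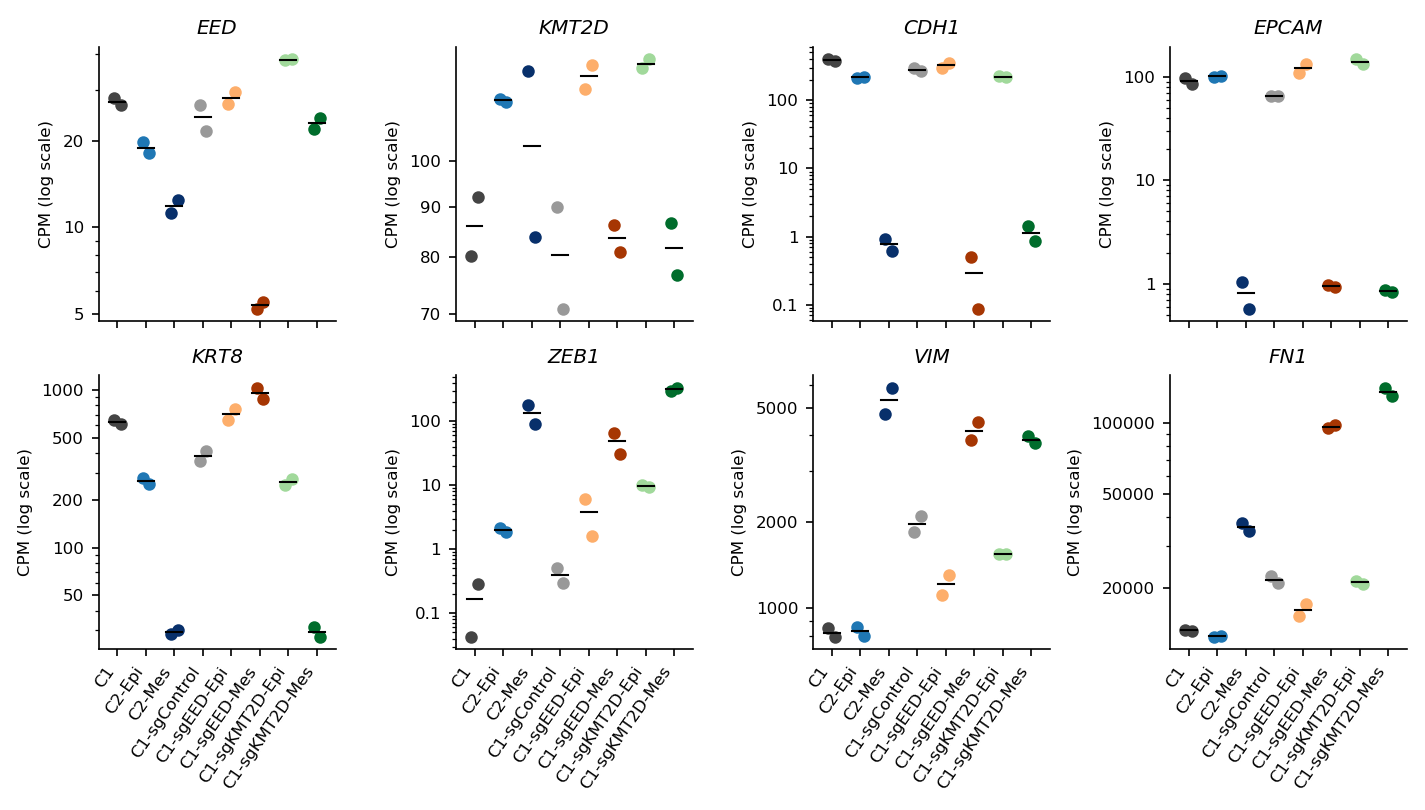
Levels of EED, KMT2D and 6 epithelial or mesenchymal genes in the 16 libraries, in CPM on log axes. Points are libraries and bars are means of the 2 libraries of a group; CDH1 lies below 2 CPM in the 6 mesenchymal libraries, while KRT8 stays at 955 ± 110 CPM in sgEED-Mes.

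The change from C2-Epi to C2-Mes is the transition of unedited cells. CDH1, which encodes E-cadherin, fell from 216 ± 7.05 to 0.771 ± 0.232 CPM (log2 -8.19) and EPCAM from 101 ± 2.72 to 0.813 ± 0.337. So did the desmosomal gene DSP from 1262 ± 32.2 to 3.05 ± 1.47, and GRHL2, an epithelial transcription factor, from 50.9 ± 0.0943 to 0.122 ± 0.00773. The basal genes that fell included KRT14, from 1255 ± 27.6 to 9.004 ± 2.90, the hemidesmosome collagen COL17A1 from 379 ± 2.84 to 1.59 ± 1.22 and the cadherin FAT2 from 271 ± 1.23 to 0.558 ± 0.202. The surface gene CD24 fell from 132 ± 1.98 to 0.564 ± 0.0291 CPM and KRT8 from 267 ± 16.2 to 29.5 ± 1.08. In their place rose the repressors of epithelial genes ZEB1 (2.03 ± 0.201 to 134 ± 59.7 CPM) and ZEB2 (1.53 ± 0.908 to 70.1 ± 22.4), and the transcription factors PRRX1 (log2 11.34) and FOXC2 (log2 6.13).

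Of the matrix genes, COL3A1 went from 1.59 ± 0.412 to 3474 ± 1101 CPM, the proteoglycan gene LUM from 0.0746 ± 0.00326 to 172 ± 68.8, and decorin (DCN) from 0 counts in both C2-Epi libraries to 205 ± 74.9, at least 1831-fold higher. VIM rose from 829.5 ± 40.9 to 5313 ± 777 CPM, FN1 by log2 1.54, the receptor gene PDGFRA by log2 8.92 and LTBP1, which binds latent TGF-beta, by log2 6.22. SNAI2, another repressor of epithelial genes, fell from 174 ± 4.84 to 67.6 ± 37.6 CPM (adjusted p = 0.0018, and 0.092 when only the compared libraries were fitted). CDH2, which encodes N-cadherin, rose by log2 1.73 (adjusted p = 0.0014, and 0.077 in that fit). Of the other genes named so far for this transition, the highest adjusted p was that of ZEB1 (adjusted p = 2.0e-06).

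In total 3845 genes rose and 3401 fell from C2-Epi to C2-Mes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 18285 genes). With only the 4 compared libraries fitted, 3361 changed in place of 7246. The main fit shares 1 spread per gene across groups, so p-values of comparisons with the noisier C2-Mes can be too low. In the epithelial list 0 of 38 measured genes rose, 30 fell and 8 did not pass (1 and 33 adjusted over the list alone), with a median log2 change of -4.87. Epithelial genes had camera adjusted p = 1.2e-20, and adjusted p = 0.014 with an estimated correlation. In the basal list 0 of 25 measured genes rose, 24 fell and 1 did not pass (0 and 24 adjusted over the list alone). Basal genes had camera adjusted p = 2.3e-21, and adjusted p = 0.014 with an estimated correlation. In the mesenchymal list 21 of 28 measured genes rose, 2 fell and 5 did not pass (22 and 2 adjusted over the list alone). Mesenchymal genes had camera adjusted p = 3.4e-09, and adjusted p = 0.028 with an estimated correlation. In the matrix list 26 of 33 measured genes rose, 3 fell and 4 did not pass (26 and 4 adjusted over the list alone), with a median of 4.72, or 4.69 with bounds for members at 0. Matrix genes had camera adjusted p = 7.5e-13, and adjusted p = 0.023 with an estimated correlation. Interferon-response genes rose, such as IFI44L (0.740 ± 0.231 to 56.4 ± 14.3 CPM) and OAS2, which encodes a sensor of double-stranded RNA (log2 3.23). In this list 17 of 35 measured genes rose, 3 fell and 15 did not pass (17 and 3 adjusted over the list alone). Interferon-response genes had camera adjusted p = 2.4e-04, and adjusted p = 0.10 with an estimated correlation. In the cell cycle list 0 of 30 measured genes rose, 21 fell and 9 did not pass (0 and 21 adjusted over the list alone). Cell cycle genes had camera adjusted p = 3.7e-07, and adjusted p = 0.16 with an estimated correlation. NF-kB target genes had no call as a list: 8 of 29 measured genes rose, 7 fell and 14 did not pass (8 and 7 adjusted over the list alone), with a median of 0.10 and a mean of 0.22 against a downward camera direction. NF-kB targets had camera adjusted p = 0.69. This list depended on which C2-Mes library was used: without replicate 1, 4 rose and 18 fell (adjusted p = 0.0025, down), and without replicate 2 the list rose (adjusted p = 0.0088). Among endothelial markers 4 of 7 measured genes rose, 1 fell and 2 did not pass (4 and 1 adjusted over the list alone). Endothelial markers had camera adjusted p = 0.040, and adjusted p = 0.26 with an estimated correlation. The adjusted p was 0.11 without C2-Mes replicate 1, 0.056 without C2-Epi replicate 2 and 0.12 with a GC and length correction.

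**Figure D2:**
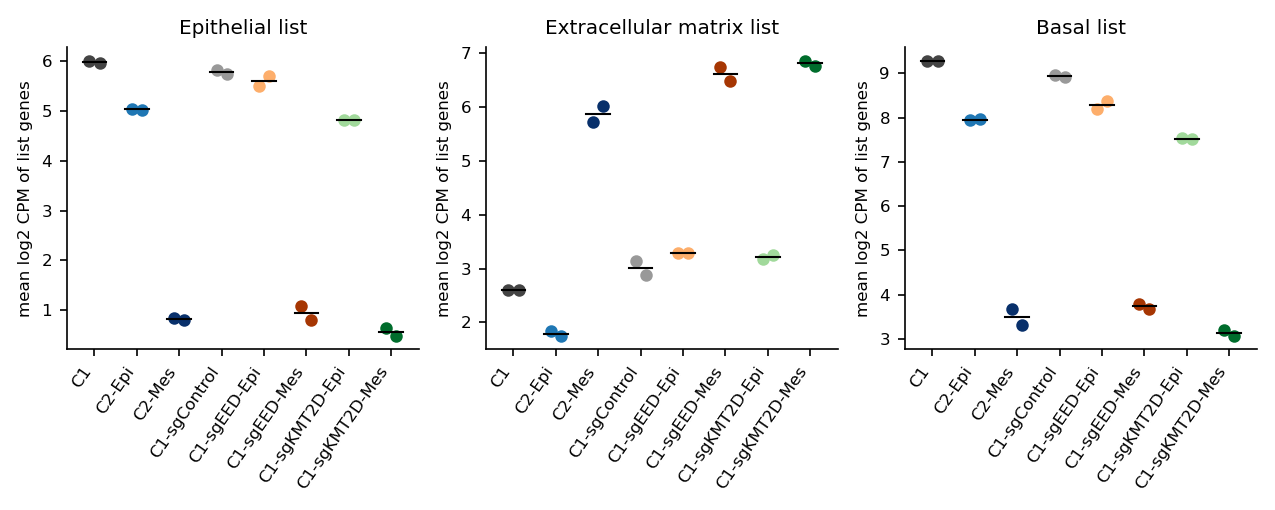
Mean log2 CPM over the genes of the epithelial, extracellular matrix and basal lists in each of the 16 libraries. Points are libraries and bars are group means; in the epithelial list the highest mesenchymal library stands at 1.09 and the lowest epithelial library at 4.81.

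From sgEED-Epi to sgEED-Mes, the edited cells also lost epithelial genes and gained matrix genes. CDH1 fell from 323 ± 36.6 to 0.298 ± 0.297 CPM, EPCAM from 121 ± 16.1 to 0.952 ± 0.0389, S100A14 from 577 ± 72.2 to 0.909 ± 0.663 and GRHL2 from 75.3 ± 7.82 to 0.215 ± 0.0550. The basal transcription factor TP63 fell from 143 ± 8.67 to 0.135 ± 0.0660 CPM, COL17A1 by log2 -8.64, KRT15 by log2 -8.92 and KRT14 by log2 -5.87. Among the genes that rose were POSTN (0.0762 ± 0.108 to 473 ± 159.9 CPM), COL3A1 (18.3 ± 2.45 to 3685 ± 579), the proteoglycan gene BGN (log2 7.63) and TAGLN, a smooth muscle actin-binding gene (12.1 ± 1.94 to 911 ± 137). The receptor gene PDGFRB rose too (log2 5.71), as did the collagen receptor gene ITGA11 (0.129 ± 0.0333 to 561 ± 103). LRRC32, which presents latent TGF-beta at the cell surface, was at 0 in both sgEED-Epi libraries and at least 596-fold higher in sgEED-Mes, and WNT7A was at 0 in both sgEED-Mes libraries and at least 111-fold lower. ZEB1 rose to 48.5 ± 24.5 CPM (log2 3.68), ZEB2 to 66.0 ± 5.65 and PRRX1 to 14.6 ± 3.402, VIM rose by log2 1.78 and FN1 by log2 2.59.

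KRT8 was at 703 ± 75.0 CPM in sgEED-Epi and 955 ± 110.4 in sgEED-Mes (log2 0.44, adjusted p = 0.021). Its adjusted p was 0.19 without sgEED-Mes replicate 1 and 0.18 without sgEED-Epi replicate 1, 0.095 without the filter on low counts and 0.11 when only the compared libraries were fitted. CD24 fell from 337 ± 27.1 to 31.8 ± 10.8 CPM. CDH2 rose from 79.1 ± 1.70 to 183 ± 40.9 (adjusted p = 0.011, and 0.096 without sgEED-Mes replicate 2 and 0.067 without sgEED-Epi replicate 2). SNAI2 was at 134 ± 12.7 and 196 ± 49.0 CPM and did not pass the test (adjusted p = 0.15, but 0.033 without the filter on low counts). The cytokine gene IL1A fell from 42.8 ± 6.76 to 0.109 ± 0.154 CPM, IL1B from 14.3 ± 1.01 to 0.142 ± 0.0476 and IL24 from 11.01 ± 0.707 to 0.0907 ± 0.128. The developmental transcription factors GATA4 and BARX1 were at 0 in sgEED-Epi and at least 36.7-fold and 59.3-fold higher in sgEED-Mes, and HOXA5 rose (log2 1.96). Genes named here without a p had adjusted p of at most that of IL1B (adjusted p = 2.4e-04).

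Between these states 3506 genes rose and 3167 fell. In the epithelial list 0 of 38 measured genes rose, 36 fell and 2 did not pass (0 and 36 adjusted over the list alone), with a median log2 change of -5.14. The test of epithelial genes gave camera adjusted p = 9.8e-31, and adjusted p = 0.011 with an estimated correlation. In the basal list 0 of 25 measured genes rose, 25 fell and 0 did not pass (0 and 25 adjusted over the list alone). The test of basal genes gave camera adjusted p = 7.6e-24, and adjusted p = 0.014 with an estimated correlation. In the mesenchymal list 24 of 28 measured genes rose, 0 fell and 4 did not pass (25 and 0 adjusted over the list alone). The test of mesenchymal genes gave camera adjusted p = 3.1e-12, and adjusted p = 0.015 with an estimated correlation. In the matrix list 27 of 33 measured genes rose, 1 fell and 5 did not pass (27 and 1 adjusted over the list alone). The test of matrix genes gave camera adjusted p = 3.7e-15, and adjusted p = 0.015 with an estimated correlation. Among transcription factors known to drive this transition 9 of 16 measured genes rose, 3 fell and 4 did not pass (9 and 3 adjusted over the list alone). These factors had camera adjusted p = 0.039, and adjusted p = 0.34 with an estimated correlation, but adjusted p = 0.13 with the GC and length correction and 0.10 without sgEED-Mes replicate 2. For developmental transcription factors 31 of 59 measured genes rose, 10 fell and 18 did not pass (32 and 13 adjusted over the list alone), with a median of 1.14. Developmental factors had camera adjusted p = 0.0053, and adjusted p = 0.16 with an estimated correlation. For HOX genes 12 of 30 measured genes rose, 1 fell and 17 did not pass (13 and 1 adjusted over the list alone). HOX genes had camera adjusted p = 0.014, and adjusted p = 0.37 with an estimated correlation. For interferon-response genes 21 of 35 measured genes rose, 2 fell and 12 did not pass (23 and 3 adjusted over the list alone). The test of interferon-response genes gave camera adjusted p = 4.1e-05, and adjusted p = 0.070 with an estimated correlation. IFI44L stood at log2 4.31 and XAF1 at log2 4.04. The NF-kB list fell: 1 of 29 measured genes rose, 16 fell and 12 did not pass (1 and 16 adjusted over the list alone), with a median of -1.08. The test of NF-kB targets gave camera adjusted p = 1.0e-04, and adjusted p = 0.59 with an estimated correlation. In the cholesterol synthesis list 1 of 25 measured genes rose, 17 fell and 7 did not pass (1 and 17 adjusted over the list alone). Cholesterol genes had camera adjusted p = 3.4e-04, and adjusted p = 0.59 with an estimated correlation. For cell cycle genes 0 of 30 measured genes rose, 2 fell and 28 did not pass (0 and 0 adjusted over the list alone), with a median of 0.06. The test of cell cycle genes gave camera adjusted p = 0.97. Among inhibitors of cyclin-dependent kinases 4 of 8 measured genes rose, 0 fell and 4 did not pass (6 and 0 adjusted over the list alone). The inhibitors had camera adjusted p = 0.026, and adjusted p = 0.14 with an estimated correlation, but adjusted p = 0.063 without sgEED-Epi replicate 1. Among surface genes used to sort these states 2 of 9 measured genes rose, 4 fell and 3 did not pass (2 and 4 adjusted over the list alone). Sort markers had camera adjusted p = 0.019, and adjusted p = 0.14 with an estimated correlation.

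From sgKMT2D-Epi to sgKMT2D-Mes epithelial genes fell and matrix genes rose as well, and a broad interferon response appeared. CDH1 fell from 220.2 ± 5.73 to 1.15 ± 0.387 CPM, EPCAM from 139.9 ± 10.3 to 0.855 ± 0.0332, and the splicing factor ESRP1 from 101 ± 9.81 to 0.451 ± 0.105. The keratin gene KRT5 fell from 3725 ± 65.8 to 21.9 ± 1.78, KRT6A from 2309.9 ± 29.4 to 8.497 ± 0.999 and KRT8 from 262 ± 15.4 to 29.3 ± 2.90. CD24 went from 176 ± 4.79 to 1.15 ± 0.0841. ZEB1 rose from 9.74 ± 0.655 to 317 ± 22.8 CPM, PRRX1 from 0.128 ± 0.0690 to 55.2 ± 1.62 and TWIST1, another driver of this transition, from 9.43 ± 1.90 to 44.2 ± 1.64. COL3A1 rose from 26.1 ± 2.36 to 10415 ± 81.5 CPM, the collagen-processing gene PCOLCE from 0.948 ± 0.214 to 357 ± 16.5 and PDGFRA from 1.02 ± 0.367 to 90.5 ± 2.73. THY1 rose from 67.1 ± 4.90 to 645 ± 37.0, CDH2 from 10.8 ± 1.53 to 80.2 ± 0.0676 and VIM from 1541 ± 0.911 to 3862 ± 151. FN1 reached 136150.0 ± 7753 CPM (log2 2.69). All genes named in these 2 paragraphs on sgKMT2D passed the test, SAA1 with the highest adjusted p, 7.2e-04.

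Genes induced by interferon rose together: MX2 by log2 8.40, XAF1 from 0.0532 ± 0.0752 to 19.4 ± 2.52 CPM and IFITM1, a restriction factor of viral entry, from 0.0576 ± 0.0313 to 11.4 ± 0.693. In this list 32 of 35 measured genes rose, 0 fell and 3 did not pass (33 and 0 adjusted over the list alone), with a median log2 change of 3.69. Interferon-response genes had camera adjusted p = 8.8e-17, and adjusted p = 0.011 with an estimated correlation. Antigen presentation followed, with HLA-B at 27.5 ± 4.50 and 159.9 ± 0.180 CPM and HLA-DMA at log2 3.72: 16 of 23 measured genes rose, 2 fell and 5 did not pass (17 and 2 adjusted over the list alone). Antigen presentation genes had camera adjusted p = 3.5e-04, and adjusted p = 0.14 with an estimated correlation. TGF-beta pathway genes moved both ways. CCN2 rose from 47.8 ± 3.48 to 824 ± 19.8 CPM, whereas TGFBI fell from 593 ± 24.6 to 25.1 ± 2.49 and PMEPA1 from 276 ± 8.27 to 15.9 ± 1.13, and the list had no call. In it 11 of 30 measured genes rose, 9 fell and 10 did not pass (11 and 10 adjusted over the list alone). TGF-beta and BMP genes had camera adjusted p = 0.98. Cell cycle genes fell, such as MYBL2 (log2 -2.32) and the mitotic kinase gene AURKA (log2 -2.06). In this list 0 of 30 measured genes rose, 24 fell and 6 did not pass (0 and 25 adjusted over the list alone), with a median of -1.17. Cell cycle genes had camera adjusted p = 5.0e-08, and adjusted p = 0.14 with an estimated correlation. The NF-kB list fell, with IL1A at log2 -6.95 and the acute-phase gene SAA1 at log2 -6.29. In this list 1 of 29 measured genes rose, 12 fell and 16 did not pass (1 and 12 adjusted over the list alone), with a median of -1.01, or -0.87 with bounds for members at 0. NF-kB targets had camera adjusted p = 0.0056, and adjusted p = 0.68 with an estimated correlation. In the cholesterol list 4 of 25 measured genes rose, 13 fell and 8 did not pass (4 and 15 adjusted over the list alone). The test of cholesterol genes gave camera adjusted p = 0.017, and adjusted p = 0.70 with an estimated correlation.

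In all, 4903 genes rose and 4391 fell. In the epithelial list 0 of 38 measured genes rose, 34 fell and 4 did not pass (0 and 34 adjusted over the list alone). Epithelial genes had camera adjusted p = 4.9e-20, and adjusted p = 0.014 with an estimated correlation. In the basal list 0 of 25 measured genes rose, 24 fell and 1 did not pass (0 and 24 adjusted over the list alone). Basal genes had camera adjusted p = 3.8e-18, and adjusted p = 0.015 with an estimated correlation. In the mesenchymal list 22 of 28 measured genes rose, 1 fell and 5 did not pass (23 and 1 adjusted over the list alone). Mesenchymal genes had camera adjusted p = 2.8e-08, and adjusted p = 0.034 with an estimated correlation. In the matrix list 27 of 33 measured genes rose, 3 fell and 3 did not pass (27 and 3 adjusted over the list alone). Matrix genes had camera adjusted p = 2.2e-11, and adjusted p = 0.029 with an estimated correlation. Developmental transcription factors moved both ways: 15 of 59 measured genes rose, 16 fell and 28 did not pass (15 and 16 adjusted over the list alone), with a median of 0.00 and a mean of -0.04. The test of developmental factors gave camera adjusted p = 0.72. Among neural markers 5 of 7 measured genes rose, 0 fell and 2 did not pass (5 and 0 adjusted over the list alone). The test of neural markers gave camera adjusted p = 0.0083, and adjusted p = 0.11 with an estimated correlation. In the COMPASS list, of KMT2 genes and their partners, 0 of 10 measured genes rose, 5 fell and 5 did not pass (0 and 5 adjusted over the list alone). COMPASS genes had camera adjusted p = 0.17, but adjusted p = 0.024 without the filter on low counts.

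**Figure D3:**
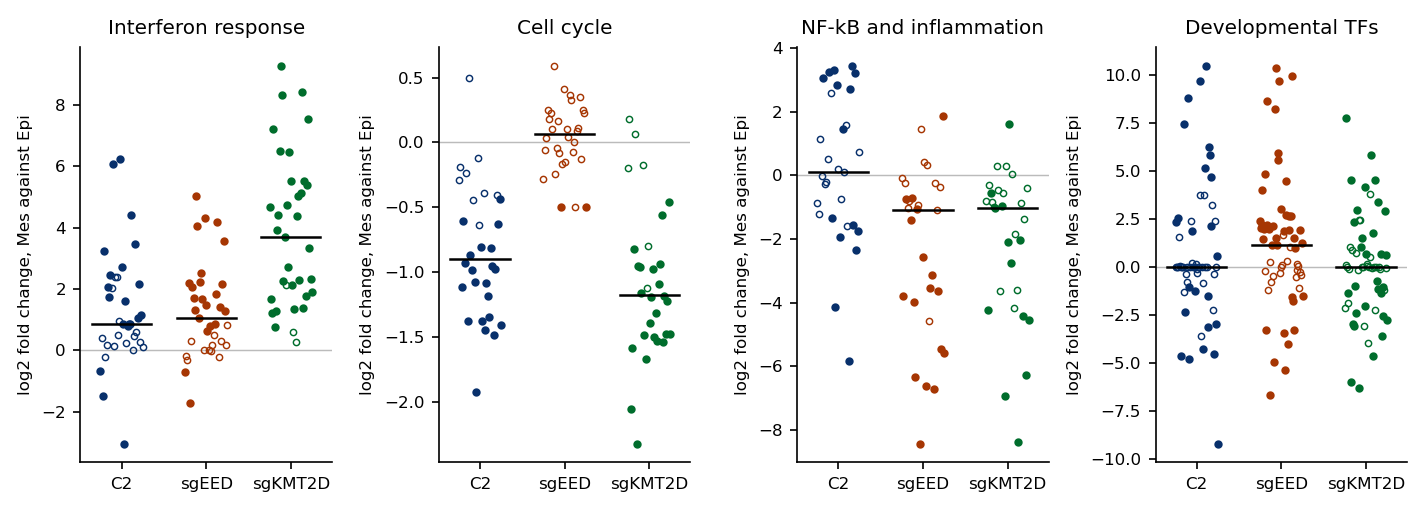
Log2 fold change from the epithelial to the mesenchymal state for each measured gene of 4 lists, in C2, sgEED and sgKMT2D cells. Filled points passed the edgeR test, open points did not, and bars are list medians, which for interferon-response genes are 0.86, 1.06 and 3.69; genes at 0 counts in 1 state are drawn at their fitted value, which is no bound.

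Many of these changes were shared. Of the 18285 genes tested, 1407 rose in all 3 transitions, where 198 would be expected of independent lists, and 1286 fell in all 3, where 141 would be expected. The transitions use separate libraries, so no shared control adds to this overlap. Across genes, log2 changes correlated with r = 0.50 between C2 and sgEED, 0.58 between C2 and sgKMT2D and 0.59 between sgEED and sgKMT2D, where genes are not independent replicates.

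Interaction terms tested whether the transitions, or their clones, differ. The change differed between sgEED and sgKMT2D for 3674 genes, between sgEED and C2 for 3866 and between sgKMT2D and C2 for 4410. The genes named here for interactions were chosen after their values were seen. The rise of interferon-response genes was larger in sgKMT2D than in sgEED, with a median log2 difference of -2.17 for sgEED minus sgKMT2D. Of 35 genes 27 were lower, and 29 adjusted over the list alone (camera adjusted p = 1.6e-17, and adjusted p = 0.0071 with an estimated correlation). It was also larger in sgKMT2D than in C2, by a median of 2.04 (23 of 35 higher, 27 adjusted over the list alone; adjusted p = 1.7e-14, and adjusted p = 0.0073 with an estimated correlation). The cell cycle list changed less in sgEED than in sgKMT2D, with a median log2 difference of 1.19 (19 of 30 higher, 22 adjusted over the list alone; adjusted p = 1.2e-10, and adjusted p = 0.20 with an estimated correlation). The changes of KRT8, DSP and CD24 were higher in sgEED than in C2, by log2 3.62, 8.72 and 4.46, and than in sgKMT2D, by 3.60, 4.35 and 3.83. The interaction counts depended on the libraries, as given below, and that of sgEED and C2 was 2130 when only the compared libraries were fitted.

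The mesenchymal states were also compared with each other. In sgEED-Mes KRT8 stood at 955 ± 110.4 CPM against 29.3 ± 2.90 in sgKMT2D-Mes, KRT18 at 323 ± 35.2 against 18.0 ± 0.907, DSP at 998 ± 128 against 49.1 ± 0.668 and CD24 at 31.8 ± 10.8 against 1.15 ± 0.0841. TGFBI was at 3032 ± 423 against 25.1 ± 2.49 CPM and PMEPA1 at 256 ± 12.5 against 15.9 ± 1.13, and higher too were the matrix genes POSTN (log2 4.77) and TNC (log2 4.93). The developmental transcription factors GATA4 and EMX2 were at 0 in sgKMT2D-Mes and at least 31.3-fold and 37.3-fold higher in sgEED-Mes, and EYA4 differed by log2 10.78. The Wnt modulator SFRP1 differed by log2 5.49. PDGFRA (3.39 ± 0.128 against 90.5 ± 2.73 CPM), the BMP inhibitor gene GREM1 (0.572 ± 0.0625 against 98.9 ± 7.58) and ZEB1 (48.5 ± 24.5 against 317 ± 22.8) were lower in sgEED-Mes. Also lower were the interferon-response genes OAS2 (log2 -4.62), IFI6 (-3.56) and MX1 (-3.34). The highest adjusted p here was that of ZEB1 (adjusted p = 7.3e-04).

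In this comparison 3231 genes were higher in sgEED-Mes and 2455 lower; the total of 5686 became 3569 without sgKMT2D-Mes replicate 1 and 3556 without replicate 2. Of the epithelial list 12 of 38 measured genes rose, 6 fell and 20 did not pass (13 and 6 adjusted over the list alone). The test of epithelial genes gave camera adjusted p = 0.38. For developmental transcription factors 37 of 59 measured genes rose, 7 fell and 15 did not pass (37 and 7 adjusted over the list alone), with a median log2 difference of 2.06, or 1.86 with bounds for members at 0. Developmental factors had camera adjusted p = 1.1e-10, and adjusted p = 0.014 with an estimated correlation. The interferon list was lower: 1 of 35 measured genes rose, 30 fell and 4 did not pass (1 and 30 adjusted over the list alone). The test of interferon-response genes gave camera adjusted p = 1.8e-15, and adjusted p = 0.011 with an estimated correlation. In the TGF-beta and BMP list 20 of 30 measured genes rose, 4 fell and 6 did not pass (20 and 4 adjusted over the list alone). The test of TGF-beta and BMP genes gave camera adjusted p = 1.4e-05, and adjusted p = 0.067 with an estimated correlation. In the Wnt list 13 of 31 measured genes rose, 3 fell and 15 did not pass (15 and 3 adjusted over the list alone), with a median of 1.95, or 0.92 with bounds for members at 0. Wnt genes had camera adjusted p = 1.0e-05, and adjusted p = 0.047 with an estimated correlation. In the cell cycle list 23 of 30 measured genes rose, 0 fell and 7 did not pass (23 and 0 adjusted over the list alone). The test of cell cycle genes gave camera adjusted p = 2.2e-10, and adjusted p = 0.11 with an estimated correlation. For hypoxia genes, with VEGFA at log2 1.97, 16 of 27 measured genes rose, 1 fell and 10 did not pass (16 and 1 adjusted over the list alone). Hypoxia genes had camera adjusted p = 1.9e-04, and adjusted p = 0.34 with an estimated correlation.

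Against C2-Mes, sgEED-Mes expressed genes that had no counts in C2-Mes. ITGA11, the myeloid-associated marker gene MYADM and LPL were at 0 in both C2-Mes libraries and at least 4529.8-fold, 1326-fold and 750.5-fold higher. The cardiac factor NKX2-5, WT1 and HOXD10 were at 0 as well and at least 82.0-fold, 47.5-fold and 82.0-fold higher. DSP stood at 998 ± 128 against 3.05 ± 1.47 CPM, TAGLN at 911 ± 137 against 0.819 ± 0.164 and the neural cell adhesion gene NCAM1 at 118 ± 21.9 against 0.0584 ± 0.0826. TGFBI was also higher, at 3032 ± 423 against 19.4 ± 3.98, as was the matrix gene EFEMP1 at 1031 ± 151 against 2.95 ± 1.28. The collagen receptor gene DDR2 (3.65 ± 0.993 against 327 ± 105 CPM) and GREM1 (0.572 ± 0.0625 against 162 ± 78.4) were lower. ZEB1 was lower by log2 -1.46 (adjusted p = 0.020, but 0.053 with DESeq2, 0.18 without sgEED-Mes replicate 2 and 0.24 without C2-Mes replicate 1). EDNRA and CSF3, high in C2-Mes, were lower by log2 -13.74 and -8.30, with wide spread in C2-Mes (612 ± 423 and 82.6 ± 45.9 CPM). Apart from ZEB1, adjusted p here was highest for WT1 (adjusted p = 1.2e-06).

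Here 3974 genes were higher in sgEED-Mes and 3690 lower, against 2044 and 1523 when only the compared libraries were fitted. Among developmental factors 40 of 59 measured genes rose, 5 fell and 14 did not pass (42 and 7 adjusted over the list alone), with a median of 3.02, or 2.68 with bounds for members at 0. The test of developmental factors gave camera adjusted p = 1.1e-10, and adjusted p = 0.014 with an estimated correlation. Among HOX genes 19 of 30 measured genes rose, 1 fell and 10 did not pass (19 and 1 adjusted over the list alone). HOX genes had camera adjusted p = 3.9e-05, and adjusted p = 0.14 with an estimated correlation. Among Wnt genes 18 of 31 measured genes rose, 2 fell and 11 did not pass (18 and 2 adjusted over the list alone), with a median of 1.59, or 1.43 with bounds for members at 0. The test of Wnt genes gave camera adjusted p = 3.3e-05, and adjusted p = 0.055 with an estimated correlation. In the cell cycle list 27 of 30 measured genes rose, 0 fell and 3 did not pass (27 and 0 adjusted over the list alone). Cell cycle genes had camera adjusted p = 8.7e-10, and adjusted p = 0.12 with an estimated correlation. In the cholesterol list 0 of 25 measured genes rose, 17 fell and 8 did not pass (0 and 17 adjusted over the list alone). Cholesterol genes had camera adjusted p = 3.1e-05, and adjusted p = 0.53 with an estimated correlation.

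Between sgKMT2D-Mes and C2-Mes every measured interferon-response gene differed. Among its genes MX2 was at 0 in C2-Mes and at least 64.7-fold higher, IFI6 stood at 78.2 ± 10.4 against 5.55 ± 2.14 CPM and XAF1 at 19.4 ± 2.52 against 0.399 ± 0.428. In this list 35 of 35 measured genes rose, 0 fell and 0 did not pass (35 and 0 adjusted over the list alone), with a median log2 difference of 2.07. Interferon-response genes had camera adjusted p = 1.3e-17, and adjusted p = 0.011 with an estimated correlation. CXCL13, a chemokine gene, stood at 103 ± 17.7 against 0.0584 ± 0.0826 CPM, HLA-B at 159.9 ± 0.180 against 45.4 ± 15.2 and the luminal transcription factor GATA3 at 63.9 ± 6.88 against 7.93 ± 1.27. The mesenchymal cadherin gene CDH11 stood at 286 ± 1.69 against 7.03 ± 2.94, EFEMP1 at 363 ± 25.4 against 2.95 ± 1.28 and FN1 at 136150.0 ± 7753 against 36186 ± 1945. CSF3 was lower (log2 -9.06), as were the hypoxia genes VEGFA (log2 -2.92) and CA9 (log2 -5.48), and DHCR7 (log2 -2.67). CES1 was at 0 in sgKMT2D-Mes and at least 1381-fold lower. The gene with the highest adjusted p was HLA-B (adjusted p = 3.5e-05).

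In this pair 2959 genes were higher in sgKMT2D-Mes and 3144 lower. The total of 6103 became 2112 with only the compared libraries fitted. In the matrix list 20 of 33 measured genes rose, 8 fell and 5 did not pass (20 and 8 adjusted over the list alone). The test of matrix genes gave camera adjusted p = 0.0039, and adjusted p = 0.28 with an estimated correlation. In the antigen presentation list 10 of 23 measured genes rose, 1 fell and 12 did not pass (11 and 2 adjusted over the list alone), with a median of 0.86, or 0.45 with bounds for members at 0. The test of antigen presentation genes gave camera adjusted p = 0.0072, and adjusted p = 0.26 with an estimated correlation. In the hypoxia list 3 of 27 measured genes rose, 14 fell and 10 did not pass (3 and 14 adjusted over the list alone). The test of hypoxia genes gave camera adjusted p = 0.0019, and adjusted p = 0.42 with an estimated correlation. In the cholesterol list 0 of 25 measured genes rose, 17 fell and 8 did not pass (0 and 18 adjusted over the list alone). The test of cholesterol genes gave camera adjusted p = 3.9e-05, and adjusted p = 0.54 with an estimated correlation.

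C2-Epi against C1 compares the plastic with the stable epithelial state, or 2 clones. The keratin KRT15 stood at 55.8 ± 0.624 against 1444 ± 79.8 CPM, KRT6B at 2.11 ± 0.435 against 175 ± 20.1 and the tight junction gene CLDN4 at 2.06 ± 0.463 against 16.99 ± 0.740. The protease gene PRSS8 was at 7.71 ± 1.01 against 34.9 ± 1.22, and the luminal genes GATA3 at 1.35 ± 0.494 against 12.9 ± 2.07 and AGR2 at 21.9 ± 0.272 against 125 ± 1.98. CDH1 was lower by log2 -0.84 (adjusted p = 0.014). Without C1 replicate 1 or 2 its adjusted p was 0.12 or 0.094, without C2-Epi replicate 1 or 2 0.13 or 0.11, and with C1 and sgControl pooled 0.083. Among mesenchymal regulators ZEB1 stood at 2.03 ± 0.201 against 0.164 ± 0.173 CPM (adjusted p = 0.010, and 0.089 without C1 replicate 1). ZEB2 stood at 1.53 ± 0.908 against 0.249 ± 0.0525 (adjusted p = 0.0043, and 0.054 without C2-Epi replicate 1). VIM (829.5 ± 40.9 and 820.2 ± 40.2) and FN1 (12435 ± 126 and 13165 ± 94.1) did not pass the test. The cholesterol synthesis genes MSMO1 (538 ± 67.7 against 102 ± 10.6 CPM), INSIG1 (299 ± 13.4 against 61.4 ± 10.6) and HMGCS1 (446 ± 7.73 against 109.6 ± 8.69) were higher.

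Several genes had no counts in C2-Epi. The DNA repair gene MGMT, GATA2 and MSX2 were at 0 in both libraries and at least 55.8-fold, 27.4-fold and 23.7-fold lower than in C1. IRX4 (log2 -6.40), HOXA10 (log2 -5.85), COL5A1 (log2 -9.28) and COL5A2 (log2 -4.72) were also lower. RPS6KA6 and CDHR1 were at 0 in C1 and at least 79.4-fold and 56.8-fold higher in C2-Epi, and the integrin gene ITGA4 was higher by log2 6.48. TGFBI (121 ± 3.65 against 741 ± 12.3 CPM) and THY1 (15.8 ± 2.55 against 122 ± 2.03) were lower. Among genes named so far without a p that passed the test, adjusted p was highest for HMGCS1 (adjusted p = 0.0032).

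In C2-Epi 2273 genes were higher and 3347 lower than in C1, against 3173 and 3018 without the filter on low counts and 4021 and 3929 without C2-Mes replicate 1. The total of 5620 depended on the libraries: it was 9967 when only the 4 compared libraries were fitted, 3466 without C2-Epi replicate 1, 2629 without C2-Epi replicate 2, 2963 without C1 replicate 1 and 2937 without C1 replicate 2. In the epithelial list 0 of 38 measured genes rose, 25 fell and 13 did not pass (0 and 27 adjusted over the list alone). The test of epithelial genes gave camera adjusted p = 1.9e-06, and adjusted p = 0.12 with an estimated correlation. In the basal list 0 of 25 measured genes rose, 16 fell and 9 did not pass (0 and 16 adjusted over the list alone). The test of basal genes gave camera adjusted p = 1.5e-05, and adjusted p = 0.14 with an estimated correlation. In the luminal list 0 of 17 measured genes rose, 9 fell and 8 did not pass (0 and 9 adjusted over the list alone), with a median of -1.23, or -0.92 with bounds for members at 0. Luminal genes had camera adjusted p = 0.0056, and adjusted p = 0.077 with an estimated correlation. For HOX genes 1 of 30 measured genes rose, 13 fell and 16 did not pass (1 and 14 adjusted over the list alone). The test of HOX genes gave camera adjusted p = 0.0063, and adjusted p = 0.32 with an estimated correlation, but adjusted p = 0.13 with the GC and length correction. In the antigen presentation list, with TAP1 at log2 -1.51 and PSMB9 at log2 -1.95, 0 of 23 measured genes rose, 10 fell and 13 did not pass (0 and 15 adjusted over the list alone). Antigen presentation genes had camera adjusted p = 0.0014, and adjusted p = 0.17 with an estimated correlation. In the cholesterol list 10 of 25 measured genes rose, 0 fell and 15 did not pass (10 and 0 adjusted over the list alone). Cholesterol genes had camera adjusted p = 7.7e-04, and adjusted p = 0.60 with an estimated correlation. In the hypoxia list, with EGLN3 at log2 -3.38, 1 of 27 measured genes rose, 11 fell and 15 did not pass (1 and 12 adjusted over the list alone). Hypoxia genes had camera adjusted p = 0.013, and adjusted p = 0.54 with an estimated correlation, but adjusted p = 0.084 with the GC and length correction.

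The guide control was compared with unedited C1, and the sgControl libraries differed widely from it. All 30 cell cycle genes were lower in sgControl, among them MKI67 (95.7 ± 28.8 against 891 ± 86.4 CPM), the topoisomerase gene TOP2A (48.4 ± 7.21 against 371 ± 15.2) and CENPF (10.0 ± 1.98 against 101 ± 2.58). Genes with higher levels were ATF3, a stress-induced transcription factor, at 552 ± 18.3 against 33.1 ± 7.87 CPM, and DDIT3, which encodes CHOP, at 60.0 ± 23.9 against 5.60 ± 0.121. So were CHAC1, a target of ATF4, at 55.3 ± 11.3 against 6.09 ± 0.864, ADM2 at 34.0 ± 4.51 against 3.16 ± 0.449 and STC2 at 158 ± 59.3 against 16.2 ± 0.819. VIM was higher (1971 ± 182 against 820.2 ± 40.2 CPM), as were COL5A1 (log2 2.47), FN1 (log2 0.72) and the TGF-beta feedback genes PMEPA1 (log2 1.49) and SMAD7 (log2 1.23). The keratins KRT15 (log2 -3.32) and KRT6B (log2 -2.44), the glycolysis gene PGK1 (log2 -1.05) and the interferon-response genes SAMD9 (log2 -3.01) and IFIT3 (log2 -2.17) were lower, and CNTN3 was at 0 in sgControl and at least 91.8-fold lower. The highest adjusted p of these genes was that of SMAD7 (adjusted p = 9.3e-04).

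In sgControl 2430 genes were higher and 2521 lower than in C1; the total of 4951 became 2247 without C1 replicate 1, 2496 without C1 replicate 2 and 2226 without sgControl replicate 2. In the cell cycle list 0 of 30 measured genes rose, 30 fell and 0 did not pass (0 and 30 adjusted over the list alone), with a median log2 difference of -1.498. The test of cell cycle genes gave camera adjusted p = 3.7e-22, and adjusted p = 0.023 with an estimated correlation. In the interferon list 1 of 35 measured genes rose, 17 fell and 17 did not pass (1 and 18 adjusted over the list alone). The test of interferon-response genes gave camera adjusted p = 5.7e-05, and adjusted p = 0.074 with an estimated correlation. In the TGF-beta and BMP list 9 of 30 measured genes rose, 1 fell and 20 did not pass (10 and 1 adjusted over the list alone). TGF-beta and BMP genes had camera adjusted p = 0.026, and adjusted p = 0.31 with an estimated correlation, but adjusted p = 0.055 with the GC and length correction, 0.063 without C1 replicate 2 and 0.054 without sgControl replicate 2. In the muscle marker list 2 of 3 measured genes rose, 0 fell and 1 did not pass (2 and 0 adjusted over the list alone). Muscle markers had camera adjusted p = 0.16, but adjusted p = 0.045 without the filter on low counts and 0.016 without C1 replicate 2. A list of 30 amino acid response genes, chosen after seeing the data, had 23 genes that rose and 0 that fell, with a median of 1.09 (camera adjusted p = 7.2e-14 over 13 comparisons, and adjusted p = 0.089 with an estimated correlation).

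**Figure D4:**
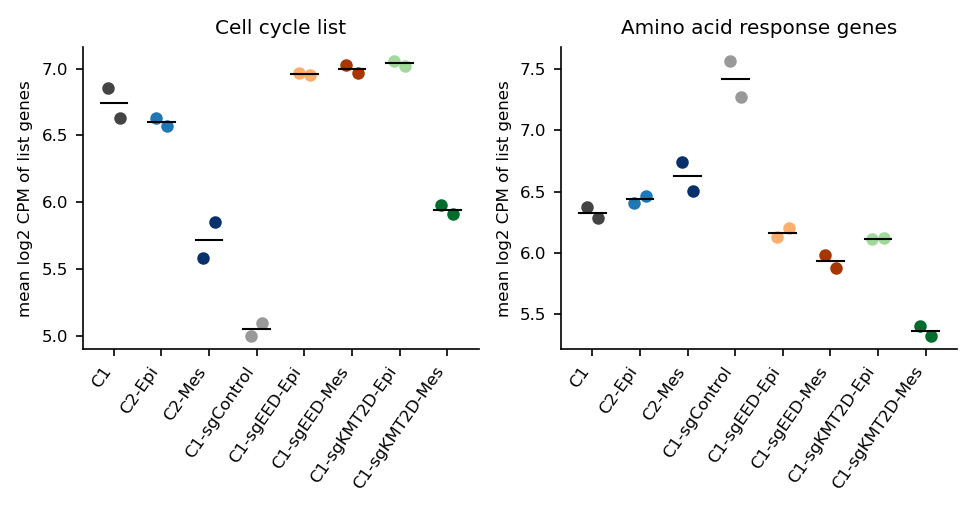
Mean log2 CPM of the cell cycle list and of the amino acid response genes in each of the 16 libraries. Points are libraries and bars are group means; both sgControl libraries lie below the other 14 in the cell cycle list and above the other 14 in the amino acid response genes.

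sgEED-Epi against sgControl compares EED-guide cells that are still epithelial with the guide control. WT1, EYA1 and PAX6, developmental transcription factors of a class that PRC2 silences in many cell types, were at 0 in both sgControl libraries and at least 56.1-fold, 64.5-fold and 20.97-fold higher in sgEED-Epi, and HOXD10 stood at 6.72 ± 0.180 against 0.0629 ± 0.0890 CPM. Also higher were the neurofilament gene NEFL at 55.2 ± 6.498 against 0.254 ± 0.0563 CPM, NCAM1 at 13.3 ± 0.481 against 0.211 ± 0.177 and CDH2 at 79.1 ± 1.70 against 0.931 ± 0.226. The integrin gene ITGA4 was at 37.2 ± 10.8 against 0.0214 ± 0.0303 and the proteoglycan gene VCAN at 203 ± 116 against 1.84 ± 0.903. The Wnt effector LEF1 and receptor gene FZD1 were higher by log2 3.81 and 2.84. ZEB1 stood at 3.82 ± 3.11 against 0.402 ± 0.144 CPM (adjusted p = 0.0026, and 0.052 without sgEED-Epi replicate 1 and 0.082 when only the compared libraries were fitted). ZEB2 stood at 2.74 ± 1.19 against 0.275 ± 0.146. KRT14 (265 ± 42.3 against 2299.7 ± 306 CPM), NGFR (2.58 ± 0.330 against 34.3 ± 2.05), LAMB3 (log2 -1.57) and COL5A1 (log2 -9.34) were lower, and CDH1 did not pass the test (323 ± 36.6 and 281 ± 18.9). The highest adjusted p of the other genes here was that of ZEB2 (adjusted p = 2.2e-04).

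The choice of control mattered. VIM was lower than in sgControl (log2 -0.71, adjusted p = 0.0011) and higher than in C1 (log2 0.56, adjusted p = 0.011), and adjusted p was 0.66 with both controls pooled. All 30 cell cycle genes rose against sgControl. Cell cycle genes had camera adjusted p = 1.8e-15, and adjusted p = 0.050 with an estimated correlation. Against C1, 5 of them rose and 0 fell (adjusted p = 0.10); C1 as the only control was chosen after seeing the data. EPCAM was higher by log2 0.89 against sgControl and by 0.40 against C1 (adjusted p = 0.082). In total 4438 genes were higher and 4492 lower than in sgControl. The total of 8930 became 5484 with both controls pooled and 4601 against C1 alone. For developmental transcription factors 25 of 59 measured genes rose, 8 fell and 26 did not pass (26 and 8 adjusted over the list alone), with a median of 0.76, or 0.50 with bounds for members at 0. Developmental factors had camera adjusted p = 0.0034, and adjusted p = 0.14 with an estimated correlation. Against C1, 29 of them rose and 3 fell. Among epithelial genes 8 of 38 measured genes rose, 18 fell and 12 did not pass (8 and 20 adjusted over the list alone), with a median of -0.52. Epithelial genes had camera adjusted p = 0.20. Against C1, 3 of them rose and 17 fell (adjusted p = 0.0034). The junction genes CLDN1 (log2 2.21) and CGN (log2 2.23) were higher than in sgControl and CLDN7 (log2 -1.91) lower. In the basal list 4 of 25 measured genes rose, 13 fell and 8 did not pass (4 and 13 adjusted over the list alone). Basal genes had camera adjusted p = 0.020, and adjusted p = 0.42 with an estimated correlation, but adjusted p = 0.053 with the GC and length correction. In the cholesterol list 12 of 25 measured genes rose, 1 fell and 12 did not pass (12 and 1 adjusted over the list alone). The test of cholesterol genes gave camera adjusted p = 0.013, and adjusted p = 0.70 with an estimated correlation.

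sgKMT2D-Epi was compared with sgControl as well. KRT14 stood at 53.7 ± 2.83 against 2299.7 ± 306 CPM, NGFR at 0.547 ± 0.0716 against 34.3 ± 2.05 and CLDN4 at 0.565 ± 0.0466 against 12.8 ± 1.52. The vesicle gene RAB25 was at 6.22 ± 0.832 against 66.8 ± 7.90 and the epithelial transcription factor OVOL1 at 1.30 ± 0.134 against 11.97 ± 0.995. The luminal factor SPDEF was at 0.742 ± 0.247 against 27.1 ± 3.30 and HLA-B at 27.5 ± 4.50 against 123 ± 13.2. Higher in sgKMT2D-Epi were HHIP, an inhibitor of hedgehog signalling (56.3 ± 1.67 against 0.0844 ± 0.0587 CPM), SFMBT2 (15.04 ± 0.419 against 0.0634 ± 0.0291) and VCAN (209 ± 0.468 against 1.84 ± 0.903). The matrix genes POSTN (log2 4.12) and DCN (log2 5.07) were higher. The transcription factors ZEB1 (9.74 ± 0.655 against 0.402 ± 0.144 CPM), ZEB2 (8.54 ± 0.250 against 0.275 ± 0.146) and FOXC2 (23.1 ± 3.05 against 4.68 ± 0.0383) were higher too. The cadherin gene CDH2 was at 10.8 ± 1.53 against 0.931 ± 0.226 CPM, while CDH1 did not pass the test (220.2 ± 5.73 and 281 ± 18.9; against C1 log2 -0.81, adjusted p = 0.012). Among the others here the highest adjusted p was that of ZEB1 (adjusted p = 9.8e-05).

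Against sgControl 4625 genes were higher and 5620 lower. The GC and length correction, chosen after seeing the data, kept 6830 of these calls and turned the sign of 167 (6660 and 5 for sgEED-Epi). In the basal list 0 of 25 measured genes rose, 19 fell and 6 did not pass (0 and 19 adjusted over the list alone), with a median of -1.11. The test of basal genes gave camera adjusted p = 6.9e-05, and adjusted p = 0.17 with an estimated correlation. In the epithelial list 6 of 38 measured genes rose, 24 fell and 8 did not pass (6 and 25 adjusted over the list alone). The test of epithelial genes gave camera adjusted p = 0.0044, and adjusted p = 0.33 with an estimated correlation. In the antigen presentation list 2 of 23 measured genes rose, 13 fell and 8 did not pass (2 and 14 adjusted over the list alone), with TAP1 at log2 -1.82. The test of antigen presentation genes gave camera adjusted p = 0.034, and adjusted p = 0.37 with an estimated correlation, but adjusted p = 0.059 with the GC and length correction. All 30 cell cycle genes rose, MKI67 by log2 3.43 among them. The test of cell cycle genes gave camera adjusted p = 6.3e-15, and adjusted p = 0.053 with an estimated correlation. Against C1, 7 of them rose and 1 fell, and MKI67 differed by log2 0.21 (adjusted p = 0.62, and 0.25 with both controls pooled). The interferon list moved both ways: 9 of 35 measured genes rose, 11 fell and 15 did not pass (9 and 11 adjusted over the list alone), with a median of -0.09 and an upward camera direction. Interferon-response genes had camera adjusted p = 0.89. Against C1 it fell (1 rose and 20 fell, adjusted p = 7.7e-04). VIM stood at 1541 ± 0.911 against 1971 ± 182 CPM (adjusted p = 0.046), a call that ended with any 1 library left out. With the GC and length correction its adjusted p was 0.052. Against C1, VIM was higher (log2 0.91, adjusted p = 2.6e-04). EPCAM was higher by log2 1.10. EZH2, the catalytic subunit of PRC2, was higher by log2 1.55, and by 0.69 against C1, both past the test. In the PRC2 list 8 of 11 measured genes rose, 2 fell and 1 did not pass (8 and 2 adjusted over the list alone). PRC2 genes had camera adjusted p = 0.11, but adjusted p = 0.017 without the filter on low counts. In the cholesterol list 12 of 25 measured genes rose, 4 fell and 9 did not pass (14 and 4 adjusted over the list alone). Cholesterol genes had camera adjusted p = 0.0086, and adjusted p = 0.68 with an estimated correlation. Against C1, 8 of these rose and 3 fell.

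Against sgControl 3333 genes rose and 3840 fell in both sgEED-Epi and sgKMT2D-Epi, where 1122 and 1381 would be expected of independent lists (r = 0.73 across genes, covariance 1.84). Both comparisons use the same 2 sgControl libraries. In 20 simulations with no effect of either guide, the shared libraries alone gave a median r of 0.53 and a covariance of 0.139, but a median of 0 and at most 1 gene rising in both, and 0 falling. With 1 sgControl library for each guide, chosen after seeing the data, 2130 genes rose and 2725 fell in both (683 and 904 expected, r = 0.63) when sgEED-Epi took replicate 1, and 2571 and 2899 (711 and 917 expected, r = 0.67) when it took replicate 2. A state common to both sgControl libraries stays in these counts. With separate controls (sgControl for sgEED-Epi and C1 for sgKMT2D-Epi) 1750 genes rose and 2353 fell in both (r = 0.41), and with C1 as the control of both 1364 and 1830. Without sgEED-Epi replicate 1, 2540 genes fell in both. C2-Epi against C1 shares no library with these comparisons. It had 967 rising and 1389 falling genes in common with sgEED-Epi (552 and 822 expected of independent lists), and 1069 and 1840 with sgKMT2D-Epi (575 and 1029 expected). Across genes r was only 0.107 and 0.178. All 3 differences followed GC content in 1 direction (rho -0.54 for C2-Epi, -0.51 and -0.63 for the guides), so a common GC trend can add to these overlaps.

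sgEED-Epi was also compared directly with sgKMT2D-Epi, which does not involve the controls. sgEED-Epi held more WT1 (7.14 ± 0.182 against 0.0199 ± 0.0282 CPM), HOXD10 (6.72 ± 0.180 against 0.281 ± 0.00333) and ITGA4 (37.2 ± 10.8 against 0.0598 ± 0.0845). It also held more NCAM1 (13.3 ± 0.481 against 0.569 ± 0.153) and CDH2 (79.1 ± 1.70 against 10.8 ± 1.53). Also higher in sgEED-Epi were CLDN4 at 6.21 ± 1.35 against 0.565 ± 0.0466 CPM, PRSS8 at 12.1 ± 1.75 against 1.35 ± 0.0586 and KRT14 at 265 ± 42.3 against 53.7 ± 2.83. KRT8 stood at 703 ± 75.0 against 262 ± 15.4 and SPDEF at 11.4 ± 0.167 against 0.742 ± 0.247. SFRP1 (log2 2.02), WNT7A (log2 2.68), CCN2 (log2 2.26) and NLRC5, a regulator of antigen presentation (log2 1.90), were higher. POSTN (0.0762 ± 0.108 against 23.6 ± 2.45 CPM) and the imprinted transcript SNHG14 (0.274 ± 0.01003 against 139.8 ± 2.53) were lower. ZEB1 stood at 3.82 ± 3.11 against 9.74 ± 0.655 CPM (adjusted p = 0.083, and 0.0077 without sgEED-Epi replicate 1, 0.024 with a replicate block). EED stood at 28.1 ± 1.99 against 38.2 ± 0.177 CPM (log2 -0.44, adjusted p = 0.049), and differed by log2 0.10 with the GC and length correction (adjusted p = 0.82). Without sgEED-Epi replicate 1 or 2 its adjusted p was 0.11 or 0.082, and without sgKMT2D-Epi replicate 1 or 2 0.13 or 0.11. Of the other genes, CDH2 (adjusted p = 9.1e-05) had the highest adjusted p.

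Here 2359 genes were higher in sgEED-Epi and 843 lower, against 2489 and 1726 with the GC and length correction and 2519 and 1531 without the filter on low counts. The total of 3202 became 1555 without sgKMT2D-Epi replicate 1, 1867 without sgKMT2D-Epi replicate 2 and 1785 without sgEED-Epi replicate 2. Among developmental factors 20 of 59 measured genes rose, 2 fell and 37 did not pass (26 and 2 adjusted over the list alone), with a median of 0.81, or 0.59 with bounds for members at 0. The test of developmental factors gave camera adjusted p = 7.8e-06, and adjusted p = 0.047 with an estimated correlation. Among luminal genes 8 of 17 measured genes rose, 0 fell and 9 did not pass (11 and 0 adjusted over the list alone). The test of luminal genes gave camera adjusted p = 4.2e-04, and adjusted p = 0.037 with an estimated correlation. In the epithelial list 16 of 38 measured genes rose, 0 fell and 22 did not pass (18 and 0 adjusted over the list alone). Epithelial genes had camera adjusted p = 2.1e-04, and adjusted p = 0.20 with an estimated correlation. In the Wnt list 14 of 31 measured genes rose, 2 fell and 15 did not pass (20 and 2 adjusted over the list alone), with a median of 0.73, or 0.61 with bounds for members at 0. Wnt genes had camera adjusted p = 0.0011, and adjusted p = 0.12 with an estimated correlation.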

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

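The interaction tests were planned; the genes named for them, and the tests of library shift, guide delivery, leukocyte RNA, shared fall, swapped labels and escape from decay, were chosen after the results were seen. The interaction tests of lists without 1 C2-Mes library were also added then. The GC and length correction and the amino acid response list were added after seeing the data, with their predictions written before their values were seen. Each gene or list in the next 3 paragraphs is here because its change from the epithelial to the mesenchymal state differed between groups by the interaction test. Values are log2 differences of the changes, and for lists medians.

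Between sgEED and sgKMT2D, 3674 genes differed. Higher in sgEED were the changes of TGFBI (6.94), DSP (4.35), PMEPA1 (4.06), CD24 (3.83), TAGLN (3.79), KRT8 (3.60), MYBL2 (2.43) and AURKA (2.09). Lower were those of OAS1 (-5.36), IFI6 (-5.18), PDGFRA (-5.03) and EED (-1.66). Among lists the median was 1.22 for developmental transcription factors, 1.28 for Wnt genes and 1.19 for cell cycle genes (adjusted p = 7.0e-04, 0.030 and 1.2e-10, but 0.20, 0.38 and 0.20 with an estimated correlation), and -2.17 for interferon-response genes, which held.

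Between sgEED and C2, 3866 genes differed. Higher in sgEED were DSP (8.72), EFEMP1 (6.90), TAGLN (6.54), KRT17 (4.60), CD24 (4.46) and KRT8 (3.62), and lower PDGFRA (-7.50), CSF3 (-7.23), FOXC2 (-4.01) and EED (-1.72). List medians were 0.61 for developmental transcription factors, 1.38 for Wnt genes, 0.92 for cell cycle genes, -2.57 for NF-kB targets and -0.76 for cholesterol genes. Their adjusted p ranged from 3.0e-07 to 0.037, and from 0.36 to 0.74 with an estimated correlation. With either C2-Mes library left out, cell cycle genes kept the call (adjusted p = 1.5e-05 and 6.8e-09, but 0.61 and 0.44 with an estimated correlation). NF-kB targets lost it without replicate 1 (median -0.66, adjusted p = 0.15) and without replicate 2 kept it (-3.38, adjusted p = 3.0e-12, and 0.025 with an estimated correlation). Cholesterol genes lost it without replicate 2 (0.14, adjusted p = 0.54) but not without replicate 1 (-1.16, adjusted p = 5.7e-09, but 0.11 with it), and developmental and Wnt genes with either left out (adjusted p from 0.059 to 0.14), at medians of 0.96 and 0.78, and 1.58 and 1.28.

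Between sgKMT2D and C2, 4410 genes differed. Higher in sgKMT2D were OAS1 (5.30), CDH11 (5.09), CCN2 (4.90), IFIT1 (4.33) and HLA-B (2.84), and lower BMP2 (-5.21) and TNC (-4.81). The interferon median of 2.04 held with an estimated correlation. Medians of 0.76 for antigen presentation, -2.54 for NF-kB, -0.81 for cholesterol, -0.57 for hypoxia and -2.09 for endothelial genes had adjusted p from 0.0028 to 0.025, and from 0.36 to 0.75 with it. Without C2-Mes replicate 1 the NF-kB median was -0.25 (adjusted p = 0.63), the cholesterol median -1.11 (adjusted p = 5.7e-09, but 0.11 with it) and adjusted p of hypoxia genes 0.11. Without replicate 2 these were -3.37 (adjusted p = 1.1e-10, and 0.027 with an estimated correlation), -0.14 (adjusted p = 0.74) and 0.0010 (0.59 with it). Endothelial genes lost the call with either left out, at medians of -2.14 and -1.24, and antigen presentation kept it (adjusted p = 0.010 and 0.0084, but 0.58 and 0.59 with an estimated correlation).

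Cell cycle genes were lower in sgControl than in C1. With the GC and length correction their median was -1.70 and all 30 fell, which argues against a GC trend. Scaling centres all genes, so the list's uncorrected gap of 1.52 to their median does not test a shift of whole libraries. Guide delivery stays open, as sgEED-Epi and sgKMT2D-Epi (medians 0.24 or higher against C1) also have target genes. Of 30 amino acid response genes 23 rose in sgControl (adjusted p = 7.2e-14, but 0.089 with an estimated correlation), so a stressed or nutrient-poor state of those cultures may account for the pattern, as a hypothesis. Both comparisons against sgControl share this state, and handling that differed between cultures was not tested.

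Interferon-response genes were higher in sgKMT2D-Mes. With the GC and length correction their median change was 3.79, and leukocyte markers summed to at most 0.939 CPM there, which argues against a GC trend and leukocyte RNA. Interferon gene counts summed to 201 and 199 in its libraries (7.86 and 8.39 CPM, above the other 14), nearly all from IFNE, which lies inside MIR31HG, with the strand setting not known. C2-Mes came near, at 7.10 and 5.82 CPM, but its mean log2 CPM of interferon-response genes was 2.48 and 2.27 against 4.56 and 4.63, so these sums alone do not account for the pattern, and interferon transcribed by the cells stays an open hypothesis. A direct effect of the KMT2D guide or of the clone was not tested.

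EED transcripts fell most from sgEED-Epi to sgEED-Mes. The change was lower than in sgKMT2D by -1.66 (log2) and than in C2 by -1.72. In sgEED-Epi 20 developmental genes were higher than in sgKMT2D-Epi against 2 lower. These argue against an equal fall in all transitions and swapped epithelial labels. With the GC and length correction the change was -2.40. An edited transcript that escapes decay in sgEED-Epi, where EED differed from sgControl by 0.22 but by -0.59 with that correction, neither past the test, stays open because gene counts hold no sequence. That the EED-guide groups are different clones, which their differing library names leave possible, also stays open, untested.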

How the results depend on the processing

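The GC and length correction, C1 as the only control, 1 sgControl library for each guide and counts of lists under them were chosen after seeing the data; the other alternatives were planned. Over 386 gene values (not all printed), 4051 alternatives kept direction and side of the threshold, 74 lost the call, 17 gained it and 18 turned the sign. Over 253 list tests, 2411 kept the side of the threshold, 92 of them in the other direction with no call either way, 97 lost the call, 66 gained it and 2 turned a called direction. With an estimated correlation 22 of 87 lists were called.

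With 1 library left out, where the lone library is assumed to vary like the other groups, counts ranged as follows: sgControl against C1 2226 to 3538; C2-Epi against C1 2629 to 3466; sgEED-Epi against sgControl 6354 to 7804; sgKMT2D-Epi against sgControl 7862 to 9108; C2-Mes against C2-Epi 5402 to 8605. They were 5254 to 5744 for sgEED-Mes against sgEED-Epi, 7182 to 7644 for sgKMT2D-Mes against sgKMT2D-Epi, 1555 to 3260 for sgEED-Epi against sgKMT2D-Epi and 3556 to 5301 for sgEED-Mes against sgKMT2D-Mes. Against C2-Mes they were 6364 to 9616 for sgEED-Mes and 4042 to 8249 for sgKMT2D-Mes. Interactions ranged from 2293 to 4118 (sgEED and sgKMT2D), 2744 to 5536 (sgEED and C2) and 3095 to 6749 (sgKMT2D and C2). Genes rising in all 3 transitions ranged from 1039 to 1650 and falling from 1169 to 1901, in both guides from 2325 to 3432 and 2540 to 3194, and called lists from 83 to 94. Fewer libraries in the fit leave fewer degrees of freedom.

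Fits of only the compared libraries gave 9967 for C2-Epi against C1. With C2-Mes they gave 3361 against C2-Epi, 3567 against sgEED-Mes, 2112 against sgKMT2D-Mes and 2130 for the interaction of sgEED and C2. sgEED-Epi gave 5484 with both controls pooled and 4601 against C1 alone. In both guides 1364 genes rose and 1830 fell against C1 alone, and 1750 and 2353 with separate controls. With sgControl replicate 1 for sgEED-Epi, 2130 rose in both. The shared spread can add to the C2-Mes counts, but no cause was tested.

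Signs turned for VIM in sgEED-Epi (0.56 against C1 alone) and sgKMT2D-Epi (0.91 against C1 alone, 0.14 with pooled controls). EED turned to 0.10 in sgEED-Epi against sgKMT2D-Epi and to -0.70 in sgKMT2D-Epi against sgControl with the GC and length correction. Other signs turned with no call. With that correction EED stood at -0.59 in sgEED-Epi and 0.51 in sgControl against C1, where KMT2D stood at 0.10. CDH1 in sgEED-Epi went to -0.046 with pooled controls and -0.26 against C1 alone. In C2-Epi VIM went to -0.75 with pooled controls and FN1 to 0.0011 without the filter on low counts. With 1 library left out FN1 ran from -0.015 to 0.022 there. KMT2D then spanned -0.29 to 0.032 in sgControl against C1, -0.054 to 0.12 in sgEED-Mes against sgKMT2D-Mes and -0.57 to 0.055 in C2-Mes against C2-Epi. The last was called with that correction (-0.56). The interferon list of sgKMT2D-Epi turned down against C1 alone (adjusted p = 7.7e-04), and the NF-kB list of C2-Mes turned up without C2-Mes replicate 2 (adjusted p = 0.0088), with adjusted p from 0.0025 to 0.83 when 1 library was left out. The cause was not tested.

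With the replicate number added as a block, counts stayed within 1.5 times in all 14 comparisons, such as 4863 for sgControl against C1 and 10137 for sgKMT2D-Epi against sgControl. Across 28 pairs of groups, residuals of equally numbered replicates correlated with r from -0.37 to 0.34 (median -0.00085), so the numbers do not show pairing. Log2 changes followed GC content at rho -0.63 (sgKMT2D-Epi against sgControl) to 0.45 (sgEED-Epi against sgKMT2D-Epi). With 2 libraries per group, changes near 1.5-fold were mostly missed in simulation.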

Other observations

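The genes below were chosen after their values were seen. In sgEED-Epi SNRPN, an imprinted gene of chromosome arm 15q, stood at 0.0781 CPM (unscaled library totals, group means) against 15.8 in sgControl, 17.04 in C1 and 8.28 in sgEED-Mes, and SNHG14 at 0.292 against 37.0, 104 and 58.3. SNHG14 overlaps SNRPN and UBE3A, so the 3 can share reads. UBE3A stood at 151 CPM in sgEED-Epi, 80.4 in sgControl (lowest), 173 in C2-Epi and 170 in sgKMT2D-Epi. MGMT was at 0 in C2-Epi and C2-Mes, 6.49 in C1, 9.29 in sgControl, 0.211 in sgEED-Epi and 2.86 in sgEED-Mes. EPDR1 stood at 10.3 CPM in sgEED-Epi and 7.15 in sgKMT2D-Mes, and at most 0.0218 elsewhere. No explanation was tested.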
